A study of Homo sapiens with 8 samples.

How the data were processed

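The series measured chromatin accessibility by ATAC-seq, in which a transposase inserts sequencing adapters into open DNA. Per the labels' protocols, 20000 cells per sample were used, libraries were amplified for 5 PCR cycles, and sequencing was paired-end with reads of 100 bp. The 8 samples fall into 4 groups of 2 replicates: HuT78, a human T-lymphocyte line, HuT78 DpVp, MCF7, a human breast cancer line, and MCF7 DpVp. The labels do not say what DpVp stands for. As background to the study, the DpVp sublines are romidepsin-resistant derivatives of the parental lines, selected with the drug and verapamil, a blocker of the efflux pump P-glycoprotein.

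The authors deposited one table with 1 row per peak, named by chromosome, start and end in hg38, and 10 columns of values. The names of these 10 columns match no title, description or other label of the 8 samples, and there are more columns than samples. No column was assigned by its order or its values, so none of the 10 was used, and the depth of each sample was not analysed here. Bowtie2, MACS2, DESeq2 and HOMER are named in the submitters' processing notes, with no role or version. How the authors merged peaks into one list is not given in the sources used here. Wide peaks and the pooling of all columns, including any that do not belong to the 8 samples, can both raise the covered length.

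The planned tests between groups, between lines, of gene lists across replicates, of summed regional counts and of promoters were therefore not run, nor were the other settings meant for them. Motifs and GC content were not analysed here, as no genome sequence was used. What follows was computed from the peak positions alone, after the table had been seen. The rule that was to name genes by p-value was replaced by this one: TMT1A, TMT1B and ABCB1 always, up to 4 members of each list with the highest covered share, the 3 densest and 3 sparsest regions of 5 Mb, and the genes in the blocks described. This rule was itself set after the data had been seen. Other genes are named where they were the exception in a list, or are said to have been chosen after their values were seen. The gene lists themselves were fixed before the data were examined.

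Peaks on chromosomes 1 to 22 and X were kept, and 802 peaks on the Y chromosome and on unplaced or unlocalised scaffolds were left out. Gene positions came from RefSeq genes on GRCh38.p14, the same assembly as hg38. That table gives the lower and upper end of each gene and no strand, so a gene end is either its start or its finish, and promoters were not told apart from 3' ends. METTL7A and METTL7B are listed there as TMT1A and TMT1B. Of the 323 distinct symbols in the 14 lists, 321 were found among protein-coding genes. DDX58, which was not found, is an older symbol of RIGI, which was. Coordinates are given as in the table, which does not say whether starts count from 0 or 1, so each may be off by 1 base.

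A gene's covered share is the percent of its span, with 10 kb added on each side, that lies in peaks, and its percentile is its place among all protein-coding genes. A peak was counted at a gene end if it came within 1 kb of either end. Chance values came from 100 circular shifts of the peaks within each chromosome. Assembly gaps and centromeres were not masked, so shifted peaks could land where none can be called. Chance values at gene ends may therefore be too low, and those outside genes too high. Shares carry Wilson intervals at 95% confidence, which cover counting error only. A list's median covered share was placed among 10000 random lists of the same size matched on gene length (20 strata). Such a percentile describes this peak set, and genes are not independent replicates. Covered blocks were runs of 20 kb windows, each covered at 75% or more, with a length of at least 200 kb. These block settings were chosen after the locus around TMT1A had been seen. Each block was compared with its flanks of 100 kb.

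Computations used Python 3.11.15, numpy 2.4.6, pandas 2.3.3, scipy 1.17.1 and matplotlib 3.10.9. On simulated peaks, 10 of 10 planted blocks of 400 kb were found with exact edges and no other block was called. The planted blocks began on window bounds in a sparse background of random peaks. This checked the code and does not measure edge accuracy or false blocks in the real peak set. The covered length of 200 genes was equal to a direct count in each case. Of 100 simulated random lists of 20 genes, 2 fell outside the central 95% of their matched lists. The simulated genes had independent values, so this too checked the code. It does not measure how often lists fall outside by chance in the real peak set, where neighbouring genes share cover. Alternatives tried were other windows around gene ends and genes, peak number in place of covered length, removal of wide peaks, matching on the region as well as on length, and other block and region sizes. For the gene lists, genes in covered blocks were also left out.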

Results

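Accessible chromatin was profiled in the T-lymphocyte line HuT78, the breast cancer line MCF7 and a DpVp subline of each, with 2 replicates per group and 8 samples in all. The series title names the methyltransferases METTL7A and METTL7B and resistance to thiol-based histone deacetylase inhibitors, drugs such as romidepsin that act through a free thiol. The design implies a comparison of each subline with its parent and of the changes between the 2 lines. These were not analysed here, because no column of the deposited table matched the labels of a sample. The values below describe the single list of peaks pooled over the whole table, with no replicate error. They say where peaks were called in at least part of the libraries, not in which line. Copy number was not analysed, so dense cover of a chromosome, region, block or gene need not mean more open chromatin.

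The list held 395802 peaks, of which 395000 lay on chromosomes 1 to 22 and X. Their median width was 662 bp, with quartiles of 547 and 1013 bp, and the widest reached 32169 bp. No peaks overlapped. Together they covered 366 Mb, or 12.1% of the 3029 Mb between the first and last annotated gene of each chromosome. Peaks wider than 2 kb made up 5.94% of the list and held 20.2% of the covered length.

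Peaks lay at gene ends more often than circular shifts, which also ran over assembly gaps, placed them there. Of the 395000 peaks, 36069 came within 1 kb of an end of a protein-coding gene, a share of 9.13% (95% Wilson interval 9.04 to 9.22%) against a mean of 3.84% and a range of 3.57 to 4.15% over 100 shifted peak sets. A further 49.8% lay inside protein-coding genes away from their ends (40.8% after shifting), and 41.1% lay outside them (55.4% after shifting). Peaks at gene ends were wider, with a median of 1096 bp against 660 bp inside genes and 624 bp outside. Seen from the genes, 17108 of 19974 protein-coding genes had a peak at an end, which is 85.7% (95% Wilson interval 85.2 to 86.1%) against 43.3% after shifting. With 5 kb in place of 1 kb, 23.1% of peaks lay at a gene end.

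The density of peaks differed between chromosomes. Chromosome 20 carried 264 peaks per Mb and was covered at 30.0%, more than chromosome 19, which was covered at 27.5% with 24.8 protein-coding genes per Mb against 8.36 on chromosome 20. Chromosome 17 was covered at 27.9% and chromosome 14 at 18.2%. The X chromosome was covered at 3.88% and chromosome 13 at 5.25%. Among 573 regions of 5 Mb, the median was covered at 8.49%. The 3 densest were chromosome 17 from 60 to 65 Mb at 62.9%, chromosome 14 from 100 to 105 Mb at 61.9%, and chromosome 3 from 60 to 65 Mb at 58.9%. The region on chromosome 3 held 13 protein-coding genes. Among regions with at least 20 peaks, the 3 sparsest, on the X chromosome from 90 to 95 Mb, chromosome 9 from 60 to 65 Mb and chromosome 16 from 35 to 40 Mb, were covered at 0.544%, 0.450% and 0.438%. The densest 29 regions, 5% of all, held 20.1% of the covered length.

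**Figure D1:**
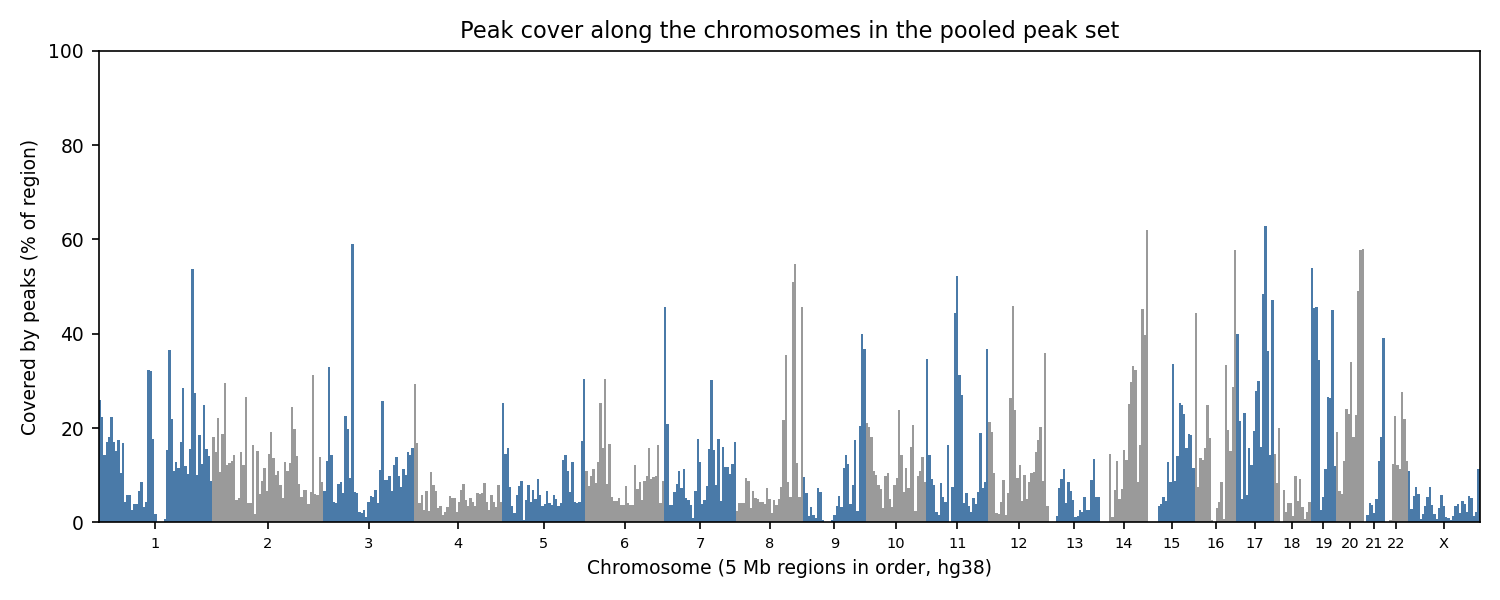
Percent of each 5 Mb region covered by peaks (y axis), with regions in order along chromosomes 1 to 22 and X (x axis); each bar is 1 region with at least 20 peaks, and colours alternate by chromosome. The highest bars reach 62.9% on chromosome 17 and 61.9% on chromosome 14, against a median of 8.49%.

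METTL7A, listed as TMT1A, encodes a methyltransferase that adds a methyl group to thiols, and it lay in one of the most densely covered parts of the peak set. The gene spans positions 50925015 to 50932508 of chromosome 12 in hg38. With 10 kb on each side it held 12 peaks, and its covered share was 94.5%, rank 170 of 19974 genes (percentile 99.2), against a median of 20.7% over all genes. The peak over its lower end ran from 50922686 to 50926213 and was 3527 bp wide. Peaks of 1746 and 3768 bp lay at its upper end, and peaks of 3383 and 559 bp lay inside it. The high rank rested on wide peaks. TMT1A stood at percentile 94.1 for the gene span alone, at 79.2 when peaks were counted per kb, and at 35.0 when only peaks under 1 kb wide were kept.

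METTL7B, listed as TMT1B and also a thiol methyltransferase, spans positions 55681736 to 55684611 of chromosome 12. With 10 kb on each side it held 8 peaks and had a covered share of 34.8% (percentile 64.4). A peak of 2008 bp from 55680954 to 55682962 lay over its lower end and one of 658 bp over its upper end. ABCB1 encodes P-glycoprotein, the efflux pump that exports romidepsin. It spans positions 87503017 to 87713295 of chromosome 7. With 10 kb on each side it held 19 peaks of 508 to 1162 bp, and its covered share was 5.93% (percentile 19.8, not matched on gene length). None lay within 1 kb of either end of this span. The widest peak, from 87600018 to 87601180, lay inside the gene. Promoters inside the span were not annotated here, so these values do not say whether an ABCB1 promoter was open. The peak from 87628024 to 87628815 also lay over the lower end of the neighbouring gene RUNDC3B.

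The cover at TMT1A was part of a block with abrupt edges. From 50720000 to 51140000 on chromosome 12, a length of 420 kb, each 20 kb window was covered at 81.8% or more, with a mean of 89.9%. The 100 kb below the block was covered at 30.4% and the 100 kb above it at 32.1%. The block held 218 peaks with a median width of 1324.5 bp. It contained all of ATF1, a CREB-family transcription factor, TMPRSS12, TMT1A, HIGD1C, SLC11A2, an iron transporter, LETMD1 and CSRNP2, and the edges lay within DIP2B and TFCP2. The covered shares of the 7 genes that it contained whole ranged from 88.7% for TMPRSS12 to 94.5% for TMT1A. DIP2B was covered at 47.4% and TFCP2 at 63.5%. When each window had to be covered at 85% or more, the run that held TMT1A was 240 kb long.

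**Figure D2:**
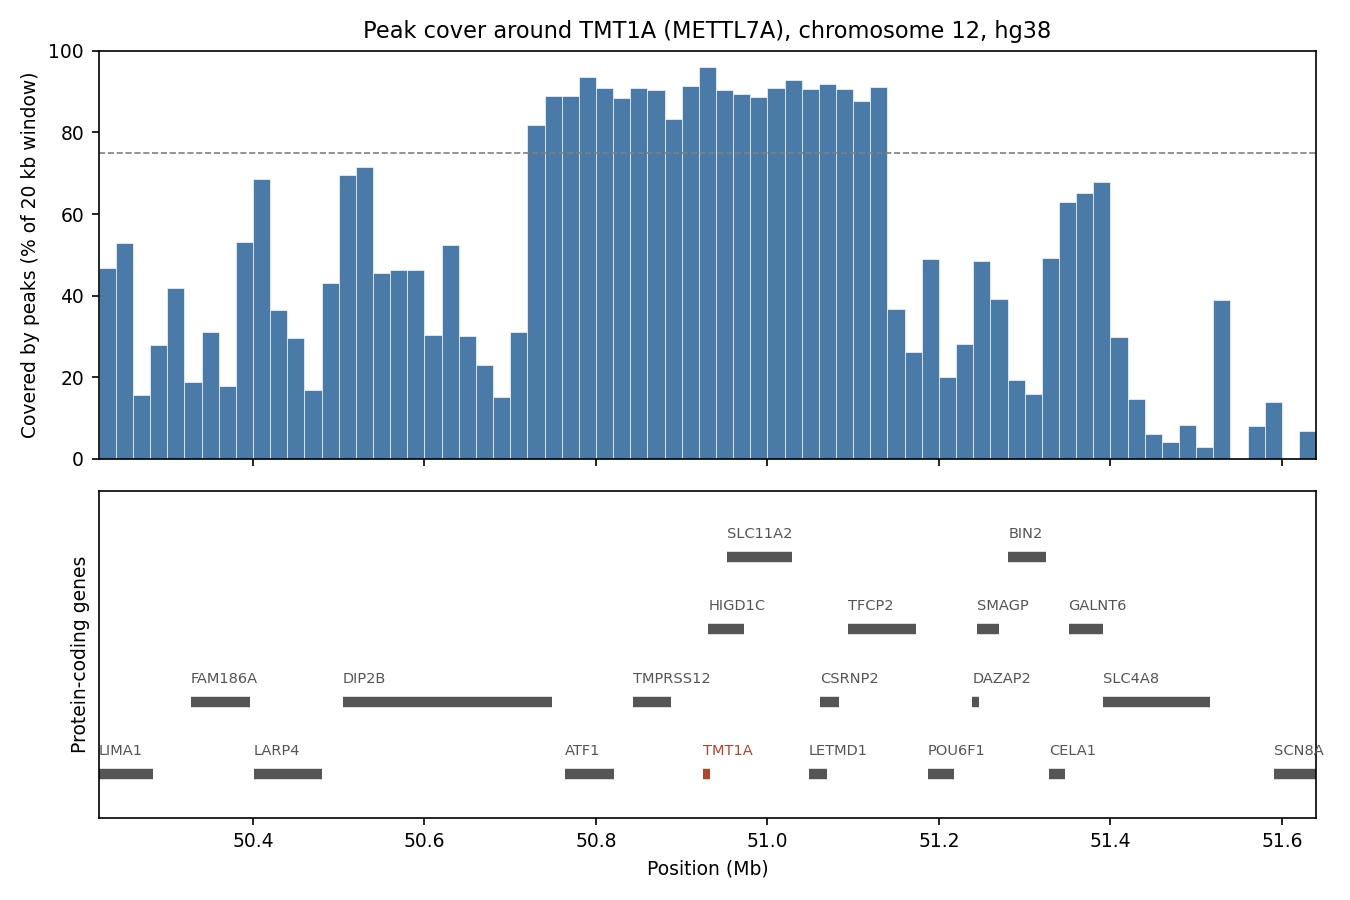
Percent of each 20 kb window covered by peaks (bars, y axis) along chromosome 12 (x axis, Mb) around TMT1A, with the spans of protein-coding genes underneath; the dashed line marks 75%. Windows from 50720000 to 51140000 are each covered at 81.8% or more, and the 100 kb on either side at 30.4% and 32.1%.

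Across the genome, 37 such blocks of at least 200 kb were found on 11 chromosomes, 15.4 Mb in all, against 66 when windows had to be covered at 65% and 20 at 85%. Chromosome 20 held 9 blocks with a summed length of 4380 kb, chromosome 3 held 5 with 3080 kb, and chromosome 17 held 3 with 1960 kb. The longest, of 1380 kb on chromosome 20 from 53560000 to 54940000, was covered at 89.4% and overlapped ZNF217, a transcription factor, BCAS1, CYP24A1, PFDN4 and DOK5. The next, of 980 kb on chromosome 3 from 63980000 to 64960000, overlapped ATXN7, PSMD6, PRICKLE2 and ADAMTS9. Blocks of 740 and 660 kb on chromosome 17 overlapped TBX2, BRIP1 and BCAS3 and, in the second, PPM1D, a phosphatase that acts on p53. The block at TMT1A ranked 13 by length. It was one of 3 in which both flanks were covered at most 0.5 times as much as the block; the others lay on chromosome 19 from 47260000 to 47900000 and on chromosome 11 from 77980000 to 78200000.

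Of the 14 gene lists, 5 had a median above the central 95% of their random lists: housekeeping genes, luminal breast genes, T cell genes, histone deacetylases and MAPK genes. Differences between lists were not tested. All 35 luminal breast and estrogen-response genes had a peak at an end, and 19 lay above 49.9%, the upper quartile of all genes. Their median covered share was 53.8%, percentile 99.99 among random lists matched on gene length, whose central 95% ran from 12.4 to 36.7%. The best covered were BCAS1 at 88.3%, GATA3 at 86.9%, the retinoic acid receptor gene RARA at 85.6% and TFF3 at 83.2%. Of the 40 T cell genes, 39 had a peak at an end, all but CTLA4, and 14 lay above that quartile. Their median was 41.1% (percentile 99.7), led by LAT, an adaptor of T cell receptor signalling, at 87.7%, GATA3, BCL11B at 76.0% and UBASH3A at 75.8%. GATA3 is in both lists.

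The medians of 3 lists for other cell types lay within the central 95% of their random lists. Fibroblast and endothelial genes had a median of 13.3% (percentile 14.3), and 11 of 15 had a peak at an end. PECAM1 at 64.6%, COL1A1 at 58.2%, ACTA2 at 42.7% and THY1 at 37.3% were the best covered. B cell and myeloid genes had a median of 32.8% (percentile 76.6), and 19 of 20 had a peak at an end. CD79A at 95.6%, CD79B at 77.6%, CD19 at 59.3% and MPO at 56.3% led that list, and CD33 had no peak. Basal and mesenchymal genes had a median of 25.8% (percentile 69.1), led by ITGA5 at 86.7%, SNAI1 at 85.7%, VIM at 64.8% and SERPINE1 at 60.4%. The 18 housekeeping genes had the highest median of the 14 lists, 65.05% (percentile 99.8), above the luminal and T cell lists. This order of medians is not matched on gene length. The length-matched random lists had medians of 31.3% for housekeeping, 21.6% for luminal and 20.7% for T cell genes. Of the housekeeping genes, 10 lay above the upper quartile of all genes, led by ATP5F1B at 89.2%, ACTB at 88.7%, GAPDH at 87.7% and RPL13A at 79.6%.

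The 15 histone deacetylase genes each had a peak at an end and a median of 53.1% (percentile 99.6), with SIRT7 at 93.4%, HDAC7 at 91.1%, HDAC10 at 71.4% and HDAC11 at 64.2%. That percentile was 86.9 when the 10 kb flanks were left out. The list includes the sirtuin genes SIRT1, SIRT2, SIRT6 and SIRT7, covered at 8.73%, 53.1%, 62.2% and 93.4%. Ranked without them, the middle HDAC gene was HDAC1 at 36.7%, so the list's median rested partly on the sirtuins. The HDAC genes alone were not compared with random lists. The class I enzymes HDAC1, HDAC2, HDAC3 and HDAC8, named after their values were seen, were covered at 36.7%, 11.1%, 54.8% and 3.20%. MAPK feedback and target genes had a median of 53.3% (percentile 99.1), led by JUNB at 89.0%, MYC at 85.3%, FOSL1 at 83.9% and SPRED3 at 81.1%. The 12 genes listed as small-molecule methyltransferases had a median of 52.5% (percentile 95.2), led by TMT1A, GAMT at 88.2%, PNMT at 85.3% and NTMT1 at 81.5%. That median lay in a gap between GNMT at 70.2% and TMT1B at 34.8%. NTMT1 acts on proteins rather than small molecules. Ranked without it, the middle gene was TMT1B at 34.8%, so the list's median rested partly on NTMT1. With NTMT1 kept, the percentile was 70.8 for peaks per kb and 71.7 without genes in covered blocks, which left out TMT1A alone. ABC transporters and the neighbours of ABCB1 had a median of 25.3% (percentile 97.0), with ABCA2 at 95.4%, ABCC10 at 71.6%, ABCC1 at 56.0% and ABCC3 at 53.5%. That percentile was 99.8 when lists were matched on the region as well.

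Among the remaining lists, the BCL2 family and death receptors had a median of 42.9% (percentile 95.3, or 97.8 for peaks per kb), with MCL1 at 92.0%, BAD at 91.1%, BCL2L1 at 87.1% and TNFRSF1A at 78.2%. The NRF2, glutathione and thioredoxin genes had a median of 36.7% (percentile 92.3), with KEAP1, the repressor of NRF2, at 91.6%, OSGIN1 at 90.8%, GPX4 at 87.2% and TKT at 81.8%. CDK inhibitors and p53 targets had a median of 37.2% (percentile 72.4), with CDKN2D at 91.8%, PLK3 at 87.5%, BTG2 at 68.0% and CDKN1B at 63.4%. Interferon-stimulated genes had a median of 30.3% (percentile 67.4), with IRF7 at 92.2%, IRF1 at 89.3%, IFITM1 at 64.0% and IFITM3 at 61.8%. No list lay below the central 95% of its random lists. If genes were independent, chance would place 0.7 of 14 lists outside it in either direction. The random lists drew single genes from all protein-coding genes, of which 991 had no peak, while some lists hold neighbouring genes. The 5 lists above the central 95% are therefore not shown to be enriched by a comparison with that number.

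**Figure D3:**
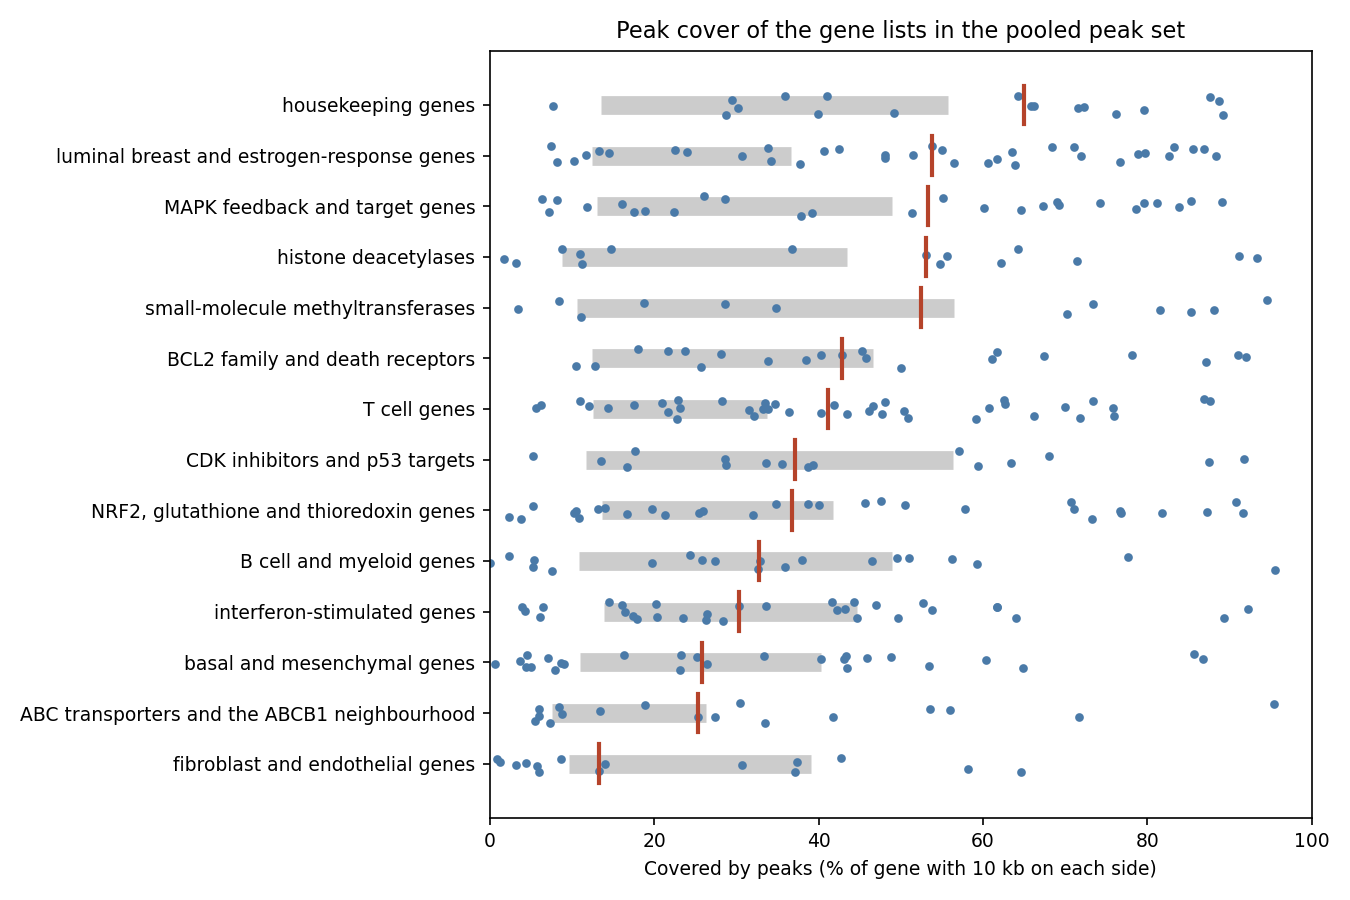
Covered share of each gene in the 14 lists (points; x axis, percent of the gene with 10 kb on each side that lies in peaks; vertical spread is for legibility), with each list's median (red line) and the central 95% of medians of 10000 random lists matched on gene length (grey bar). The medians of 5 lists lie to the right of their grey bar, the housekeeping list at 65.05%, the luminal breast list at 53.8% and the T cell list at 41.1% among them.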

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

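The alternatives below were chosen after the data were seen, since the planned ones needed values per sample and were not run. No paired analysis was possible because no column of the table could be matched to a replicate, and for the same reason no replicate could be left out. Of 56 alternatives for the 14 gene lists, 53 kept each list on its side of the central 95% of random lists. The exceptions were the histone deacetylases, at percentile 86.9 with the gene span alone, the ABC transporters, at 99.8 with matching on the region as well, and the BCL2 family, at 97.8 with peaks per kb. TMT1A stood at percentile 94.1 with the gene span alone, at 79.2 with peaks per kb and at 35.0 with peaks under 1 kb only, the last by construction, since that setting removes the wide peaks that covered the locus. With 50 kb on each side it stood at 99.3. TMT1B and ABCB1 stayed within the central 95% of genes in each setting tried. Gene ends of 500 bp in place of 1 kb lowered the share of genes with a peak at an end to 83.4%, and 5 kb raised the share of peaks at a gene end to 23.1%, as wider windows must. Block number depended on the bound: 66 blocks at 65% and 20 at 85%, against 26 with 10 kb windows and 50 with 40 kb windows. The run that held TMT1A was 420 kb long at 65% and with 10 kb windows, 400 kb with 40 kb windows and 240 kb at 85%. Neither read depth nor signal strength was used directly, though both can affect which peaks are called and how wide they are. At equal width, a weak peak in 1 library weighed as much as a strong peak in all.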

Other observations

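Each test in this part was chosen after the result was seen. Of the 321 listed genes that were found, 6 overlapped a covered block, as did 228 of all 19974 protein-coding genes, and no difference between these shares was tested. Besides TMT1A they were ABCA2, BCAS1, BCL2L1, KEAP1 and MYC. BCL2L1, which encodes an anti-apoptotic protein, overlapped a block of 380 kb on chromosome 20 from 31340000 to 31720000. MYC overlapped a block of 200 kb on chromosome 8 from 127560000 to 127760000, and a second block of 420 kb on that chromosome, from 127780000 to 128200000, held no protein-coding gene. KEAP1 overlapped a block of 440 kb on chromosome 19 that held 21 protein-coding genes.

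The block around TMT1A raises the hypothesis that the locus was present in extra copies in at least 1 of the pooled libraries. A similar number of protein-coding genes rarely came with such cover. The 400 kb centred on TMT1A was covered at 90.2%, percentile 99.9 of 12955 stretches of the same length with a similar number of such genes. The median of those stretches was 22.6%. These stretches started every 20 kb and overlapped, so they are not separate comparisons. The 400 kb lay within the block already seen, so only the cover of the other stretches was open. The high percentile is therefore partly built in. Wide peaks merged at gene ends were not the whole source of this cover. Peaks within 1 kb of an annotated gene end held 26.3% of the covered length there, a share between the bounds first set for and against this explanation. A further test on the same 400 kb left such peaks out everywhere. The 400 kb was then still covered at 66.5%, percentile 99.9 of the same stretches, whose median was then 15.1%. That percentile too is partly built in, as the 400 kb was already known to be densely covered. A gain of copies and one broad accessible domain cannot be told apart: the better covered flank had 0.357 times the block's cover, but these edges prompted the hypothesis, the lowest 20 kb window, at 81.8%, is allowed by both, and values per library were not analysed here.

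Among all 37 blocks, 3, with that at TMT1A, had both flanks covered at 0.5 times the block or less, and 29 had a flank covered at over 0.8 times the block. Several neighbouring blocks were parted only by short gaps, so that their flanks lay in another block. No gain of copies was tested for these blocks. Counting every protein-coding gene that overlapped a block, even only at its edge, there were 14.8 genes per Mb of block. All chromosomes together had 6.59 per Mb, with each gene counted once. These measures differ, since genes that cross an edge raise the first. Genes were also uneven between blocks: 1 block on chromosome 9 held 35, and 9 blocks held at most 1. Gene density does not account for every block, since 13 of the 37 had fewer genes per Mb than all chromosomes together. For the other 24 that count decides nothing. Of the 37, 36 were covered above the 99th percentile of stretches of the same length with a similar number of protein-coding genes. The exception lay on chromosome 11 from 62500000 to 62720000, at percentile 96.2. A similar number of genes thus rarely came with such cover, but blocks were picked for high cover, which partly builds in this result. No biological difference between the groups was tested for any block.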
